A study of Homo sapiens with 12 samples.

How the data were processed

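PRO-seq, which sequences the nascent RNA that engaged RNA polymerases extend in a nuclear run-on and so reads transcription rather than accumulated RNA, was measured in T47D cells, an estrogen receptor-positive human breast cancer line. The 12 libraries formed 6 groups of 2. Of these, 4 groups were grown in complete medium and given vehicle (0.1% DMSO by volume), fulvestrant, raloxifene or tamoxifen (each drug at 100 nM). The other 2 groups were starved of hormones and given vehicle or 1 nM estradiol. A time of 3 days in medium is recorded for every group. All treatments lasted 1 h. Libraries were assigned to groups by their labels, whose descriptions number the libraries of each group 3 and 4 while their titles number them 1 and 2. The numbers 3 and 4 are used here. The labels' protocol text describes the complete medium only, so starvation was taken from the group names and the series design text, and the vehicle of the estradiol arm is not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

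The authors deposited a table of raw counts, whole numbers per Ensembl gene ID, which were not normalized. Per the submitters' processing notes, cutadapt 1.8.1, Bowtie2 2.4.4 and SAMtools 1.9 were used with genome build hg38. The counting tool, the annotation, the strand setting and the counted part of each gene are not given in the sources used here. Counts of overlapping and antisense genes are therefore uncertain, and nothing here separates promoter-proximal from gene-body polymerase. Of 60605 gene IDs in the table, 60463 had a symbol in the reference list, and the 142 without one held 0.28% of counts. Where several IDs shared a symbol, the ID with the highest total was used, which left out 1195 IDs with 0.074% of counts and kept 59410 genes. Gene positions, lengths and classes came from the RefSeq table of assembly GRCh38.p14, matched by symbol, for 40393 of these genes.

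Library totals ran from 3682311 counts in raloxifene library 4 to 7856803 in raloxifene library 3. PCR duplicates cannot be told from separate molecules in such counts, so the intervals given for shares of counts cover counting error only. The libraries of each group were checked for duplicate deposition with a chi-square test over genes with at least 20 counts in the pair, and every pair differed by more than sampling noise, with a chi-square per gene from 1.2 in the starved vehicle pair to 2.29 in the raloxifene pair.

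Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low genes were removed with edgeR's filterByExpr, which left 23375 genes, library sizes were scaled by TMM, and a quasi-likelihood model with the 6 groups as its only term was fitted to all 12 libraries. Differences were tested with edgeR's quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Fold changes are given on the log2 scale with the standard error of the fit, and levels as TMM-scaled CPM, mean ± SD of the 2 libraries. The comparisons were estradiol against vehicle in starved cells, each drug against vehicle in complete medium, the drugs against each other at their shared dose and time, and starved against complete medium in vehicle.

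Fixed lists of genes were tested with limma 3.58.1 on log2 CPM with a prior count of 2: camera with a preset correlation between genes of 0.01, camera with an estimated correlation, and fry. Camera sets a list against the other genes, whereas fry asks whether the list itself moved. Fry results are those of its directional test, unless its mixed test, which counts changes in either direction, is named. The 20 lists were estrogen-induced genes, estrogen-repressed genes, immediate-early genes, nuclear receptors and cofactors, luminal epithelial markers, basal and mesenchymal markers, stromal, endothelial and blood cell markers, ribosome biogenesis, G1/S and G2/M cell cycle, growth factors with their receptors and chemokines, progestin, androgen and glucocorticoid targets, interferon-stimulated genes, the unfolded protein response, the heat shock response, cholesterol synthesis and uptake, p53 targets, the BCL2 family, RNA polymerase III and snRNA genes, and housekeeping genes. The list tests' p-values were adjusted over the 20 lists of a comparison, and counts of list members past the threshold are also given with p-values adjusted over the list alone.

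The groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 genes that rose most and the 10 that fell most among those past the threshold with a mean of at least 50 counts and no overlap of CPM between the groups, up to 4 members of each list by adjusted p, and always ESR1, GREB1, PGR, TFF1, PDZK1, MYC, CCND1, RARA, XBP1 and NRIP1. Of the 224 values named in the text by gene and comparison, 190 passed the threshold, and in all 190 both libraries of one group lay above both of the other. For the genes that rose or fell most, the rule itself required this separation. Of the 107 genes behind the 224 values, 23 overlap another tested gene by RefSeq position, and in 5 of these (FN1, GINS2, MAFF, RN7SK and TP53INP1) the other gene held more counts. TFF1 had 56 counts over all 12 libraries and was removed by the filter, so it was not tested. The results of 1 further gene named by the rule are not reported.

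The model was tested on simulated data drawn from the real library sizes and 1 mean per gene over all 12 libraries. In these data 50 genes were changed at each of 4 fold sizes. For the estradiol comparison edgeR's test recovered 18% of the genes changed 1.25-fold, 54% at 1.5-fold, 76% at 2-fold and 80% at 4-fold, with 14 false calls of 128 over 22926 genes. For the fulvestrant comparison it recovered 16%, 52%, 68% and 84%, with 9 false calls of 119 over 22932 genes. On the same data DESeq2 made 3 false calls of 95 for estradiol and 2 of 97 for fulvestrant. It recovered 6% and 14% of the genes changed 1.25-fold. Overlaps between comparisons that share control libraries are given beside the overlap of independent lists of the same sizes. They are also given beside the mean of 50 simulations, in which all 12 libraries were redrawn from 1 mean per gene. With no gene changed few are called, so the simulated overlaps cannot show how many shared calls come from the shared controls.

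The alternatives were DESeq2 1.42.0, edgeR's robust fit, DESeq2-type size factors, library sizes without TMM, no filter on low counts, a mean of at least 50 counts, the library number as a block, a fit of the groups compared alone, each library left out in turn, every gene ID on its own, and a test against a 1.5-fold change. A fit without raloxifene library 4 and a fit without genes that lack a RefSeq length or are shorter than 1000 bases were added after the data had been seen, as was a split that gives 1 shared vehicle library to each of 2 comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.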

Results

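Nascent transcription was measured by PRO-seq in 12 libraries of T47D cells, in 6 groups of 2 libraries. Cells in complete medium received vehicle, fulvestrant, raloxifene or tamoxifen. Hormone-starved cells received vehicle or estradiol. All treatments lasted 1 h. Estradiol is the main natural ligand of estrogen receptor alpha. Fulvestrant is an antagonist that also leads to loss of the receptor protein. Raloxifene and tamoxifen are selective estrogen receptor modulators, which act as antagonists or agonists depending on the tissue. Library totals were 7377576 and 6790454 counts for starved vehicle, 6584874 and 5579262 for estradiol, and 6344474 and 4981796 for complete vehicle. They were 6134826 and 5583088 for fulvestrant, 7856803 and 3682311 for raloxifene, and 7393181 and 6055972 for tamoxifen. Within groups, log2 CPM correlated across genes with r between 0.976 (raloxifene) and 0.989 (starved vehicle), where genes are not independent replicates.

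**Figure D1:**
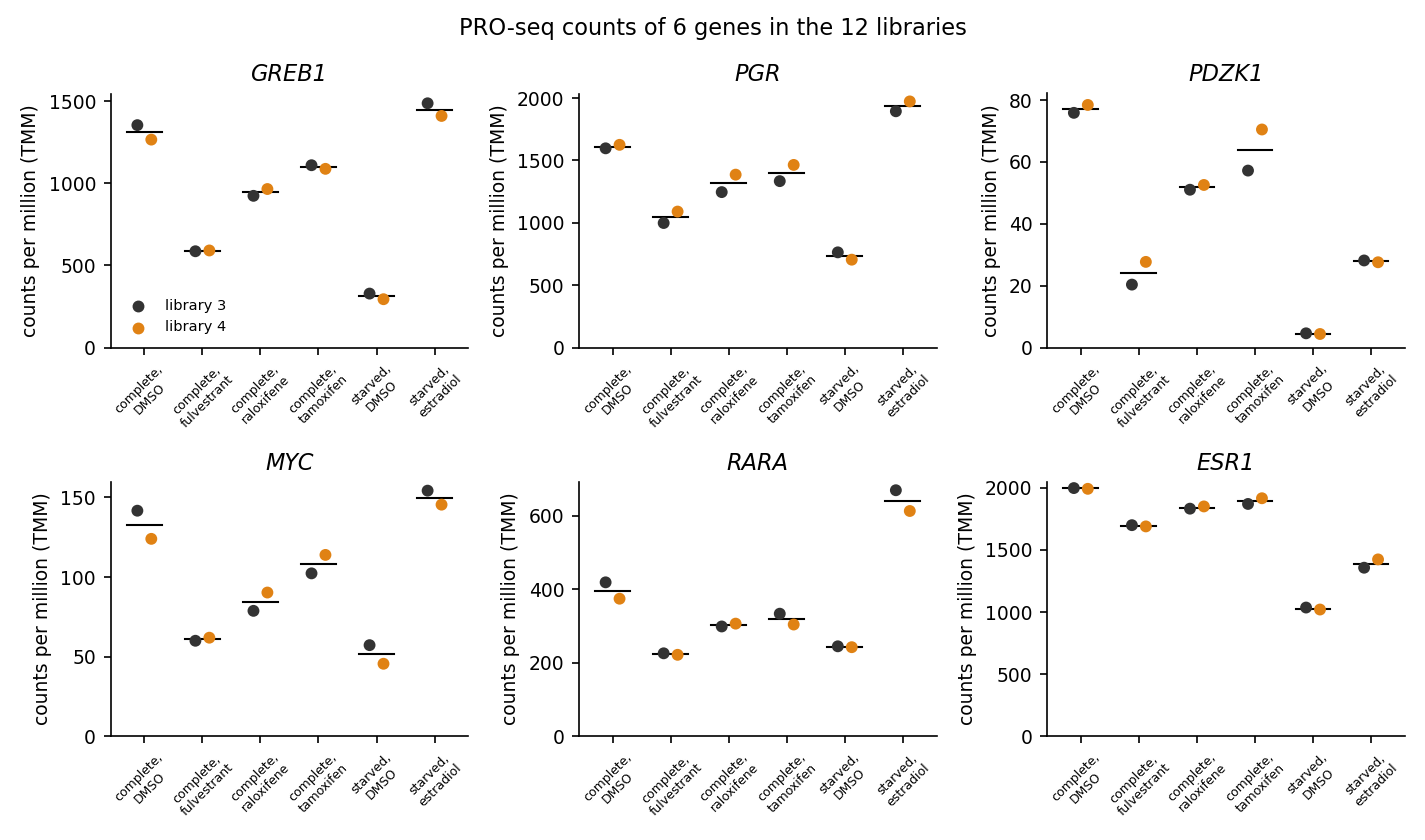
TMM-scaled CPM (vertical axes) of 6 genes in each of the 12 libraries, with library 3 and library 4 of each group as points and their mean as a line. GREB1 averaged 1310 CPM in complete medium with vehicle, 589 with fulvestrant, 311 in starved cells with vehicle and 1450 in starved cells with estradiol.

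The comparison of estradiol with vehicle asked which genes starved cells transcribe more or less within 1 h of receiving the hormone. GREB1, a cofactor of the estrogen receptor and a classical target gene (ENSG00000196208, chromosome 2, 11482888 to 11642788, hg38), rose from 311 ± 24 to 1450 ± 55 CPM (SD, n = 2), a log2 fold change of 2.22 ± 0.055 (standard error of the fit; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.1e-16). IGFBP4, which encodes a binding protein of insulin-like growth factors (ENSG00000141753, chromosome 17, 40443450 to 40457725), rose from 23.6 ± 3.4 to 219 ± 12 CPM, a log2 fold change of 3.21 ± 0.098. PGR, the progesterone receptor gene (ENSG00000082175, chromosome 11, 101029624 to 101129813), rose by 1.40 ± 0.059 to 1930 ± 56 CPM. MYC, a growth-promoting transcription factor gene (ENSG00000136997, chromosome 8, 127735434 to 127742951), rose by 1.54 ± 0.096 to 150 ± 6.2 CPM. Among genes that fell, SELENBP1, a selenium-binding protein gene, changed by -1.37 ± 0.189 and EPHA4, an ephrin receptor gene, by -1.07 ± 0.068, from 234 ± 16 to 112 ± 0.62 CPM.

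The 10 genes that rose most by the fixed rule included the long non-coding RNA LINC01016 (4.78 ± 0.271), NKAIN1 (3.35 ± 0.209), the transcription factor gene GATA4 (3.25 ± 0.198) and the potassium channel gene KCNK5 (3.01 ± 0.13). SPINK4 (2.84 ± 0.128), the receptor tyrosine kinase gene RET (2.74 ± 0.186), PDZK1 (2.63 ± 0.191) and the chemokine gene CXCL12 (2.55 ± 0.127) were also among them. ESR1, which encodes the receptor itself (ENSG00000091831, chromosome 6, 151656672 to 152129619), rose by 0.44 ± 0.040, from 1030 ± 12 to 1390 ± 47 CPM. RARA (1.40 ± 0.061), NRIP1 (1.11 ± 0.064), XBP1 (0.85 ± 0.091) and CCND1 (0.67 ± 0.115) rose as well. They encode a retinoic acid receptor, a receptor corepressor, a secretory-stress transcription factor and cyclin D1. The largest falls after SELENBP1 included those of the sialyltransferase gene ST8SIA1 (-1.12 ± 0.156), LRIG3 (-1.10 ± 0.080) and the semaphorin receptor gene NRP1 (-1.10 ± 0.225). ZNF608 (-1.09 ± 0.083), SMAD6 (-1.06 ± 0.103) and the interleukin-1 receptor gene IL1R1 (-1.06 ± 0.091) fell by similar amounts.

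Of 42 tested genes of the estrogen-induced list, 36 rose, 0 fell and 6 did not pass (38 rose when adjusted over the list alone). Their median log2 fold change was 1.40 (camera adjusted p = 9.3e-55; adjusted p = 0.0089 with an estimated correlation). Of 19 estrogen-repressed genes, 7 fell, among them CCNG2 (-0.80 ± 0.087) and LIPH (-0.68 ± 0.074). The other direction held 5 genes, among them BCL6 (0.56 ± 0.058). When adjusted over the list alone, 9 fell and 6 rose, and the list was called downward by fry (adjusted p = 0.0012) and not by camera (adjusted p = 0.15). Ribosome biogenesis genes rose in 16 of 34 cases (20 when adjusted over the list alone), including the nucleolar genes DDX21 (0.73 ± 0.082), NOLC1 (0.63 ± 0.093) and WDR43 (0.38 ± 0.071). None fell (camera adjusted p = 1.1e-13; adjusted p = 0.0097 with an estimated correlation). Interferon-stimulated genes were also called under both correlations, with a median of -0.32 over 22 genes. MX2 (-1.18 ± 0.352) and OAS3 (-0.35 ± 0.106) passed on their own (4 when adjusted over the list alone; camera adjusted p = 0.00033; adjusted p = 0.031 with an estimated correlation). MX2 was at 2.00 ± 0.25 CPM with estradiol and 4.61 ± 1.3 CPM with vehicle.

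Camera called another 5 lists upward with the preset correlation and not with an estimated one, and fry called all of these (adjusted p from 0.0017 to 0.0033) but the unfolded protein response (adjusted p = 0.056). Immediate-early genes, which respond to growth signals without new protein synthesis, rose in 10 of 32 cases (12 when adjusted over the list alone), including MAFF (1.81 ± 0.175), FOSL2 (1.03 ± 0.089) and ZFP36 (0.78 ± 0.105). The list had an adjusted p = 0.12 with an estimated correlation. In the growth factor list 5 of 21 genes rose, among them the cytokine receptor gene IL6ST (1.18 ± 0.067), TGFA (1.07 ± 0.097), AREG (1.06 ± 0.137) and IGF1R (0.56 ± 0.044). Of the others 2 fell (6 and 2 when adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). Heat shock response genes rose in 3 of 16 cases (4 when adjusted over the list alone), led by the cochaperone gene FKBP4 (1.68 ± 0.068), with DNAJA1 (0.67 ± 0.096) and HSP90AB1 (0.45 ± 0.091). The list had an adjusted p = 0.16 with an estimated correlation. Progestin, androgen and glucocorticoid targets rose in 4 of 17 cases (5 rose and 1 fell when adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). In the unfolded protein response 2 of 22 rose and 1 fell (3 and 1 when adjusted over the list alone; adjusted p = 0.25 with an estimated correlation).

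Cell cycle genes moved little by this time. Of 29 G1/S genes 2 rose, CCND1 and GINS2 (0.61 ± 0.099), and SKP2 fell (-0.40 ± 0.108; 2 and 2 when adjusted over the list alone). Of 22 G2/M genes 0 passed edgeR's quasi-likelihood test over all genes or over the list alone, for example TOP2A at 0.21 ± 0.081. Luminal epithelial markers went both ways, with 6 of 18 higher, including KRT8 (0.48 ± 0.058) and ELF3 (0.53 ± 0.069). The 4 lower ones included TFAP2A (-0.54 ± 0.052) and ERBB3 (-0.39 ± 0.064), and the counts adjusted over the list alone were the same. Among 24 nuclear receptors and cofactors 5 rose and 7 fell (5 and 8 when adjusted over the list alone). Of the 13 basal and mesenchymal markers tested, 2 rose and 1 fell (3 and 2 when adjusted over the list alone), and none of the 5 tested markers of stromal, endothelial and blood cells passed. No list in this paragraph was called by camera, with adjusted p from 0.36 to 0.92, while fry called the nuclear receptors (adjusted p = 0.0017) and the G1/S genes (adjusted p = 0.022) upward.

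With edgeR's quasi-likelihood test, 1177 genes were higher and 874 lower with estradiol, out of 23375. Of these, 289 of the higher and 40 of the lower changed at least 2-fold. The share of higher genes was 57.4%, and with library sizes not scaled by TMM it was 45.7%, 1024 higher and 1217 lower. With the library number as a block, a pairing that the labels do not state, 1597 were higher and 1407 lower. DESeq2 called 702 higher and 376 lower. Leaving out a library gave 802 and 443 without starved vehicle library 3, and 701 and 454 without starved vehicle library 4. It gave 821 and 504 without estradiol library 3, and 822 and 485 without estradiol library 4.

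**Figure D2:**
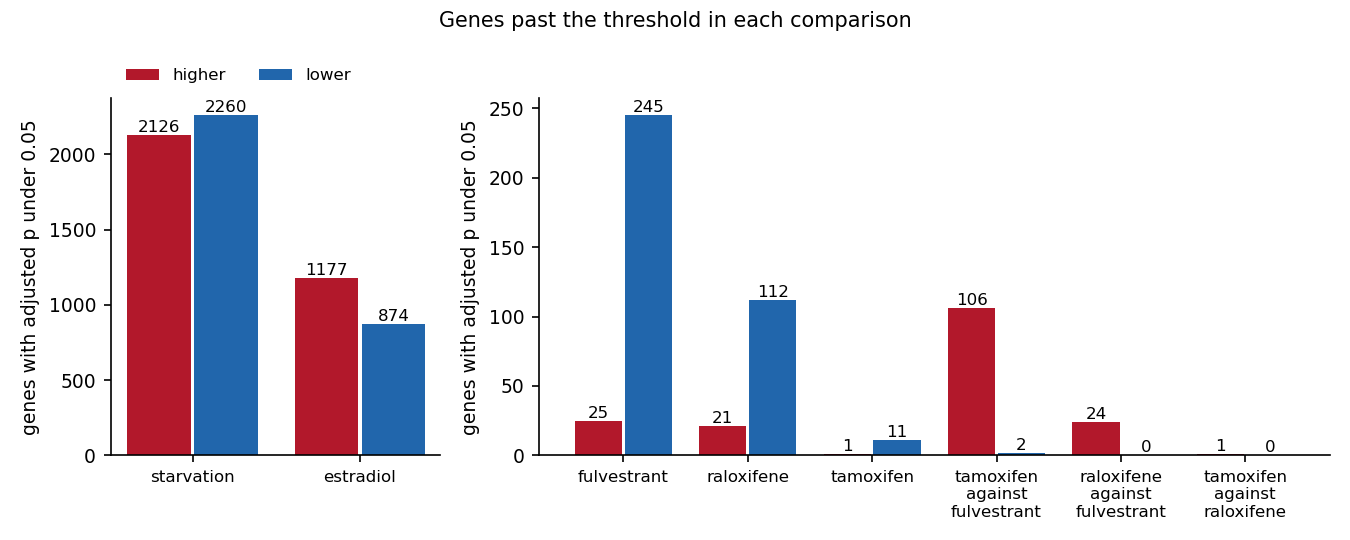
Number of genes (vertical axes, drawn on separate scales in the left and right panels) with an adjusted p under 0.05 in each comparison, with genes higher in red and lower in blue. Starvation and estradiol each changed over 2000 genes, and among the drugs fulvestrant lowered 245, raloxifene 112 and tamoxifen 11.

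Starved and complete medium were compared in the vehicle libraries, which gives the transcription from which estradiol started. PDZK1, a scaffold protein gene (ENSG00000174827, chromosome 1, 145670852 to 145707400), was at 4.50 ± 0.16 CPM in starved and 77.1 ± 1.8 CPM in complete medium, a log2 fold change of -4.09 ± 0.160. GATA4 (-3.91 ± 0.183), CXCL12 (-3.18 ± 0.12), OLFM1 (-2.88 ± 0.115), the prostaglandin E synthase gene PTGES (-2.56 ± 0.141) and IGFBP4 (-2.52 ± 0.103) were also far lower. WT1 was lower too (-2.82 ± 0.183), where the strand setting is unknown and an antisense gene overlaps. GREB1 changed by -2.07 ± 0.055 on the log2 scale and ESR1 by -0.96 ± 0.040. PGR, MYC, CCND1, RARA, XBP1 and NRIP1 changed by -1.13, -1.37, -1.04, -0.71, -0.66 and -1.07. The genes that rose most included the non-coding RNA LINC01845, from 1.3 ± 0.4 to 44.8 ± 0.72 CPM (5.04 ± 0.222), the cation channel gene TRPM8 (2.4 ± 0.149), TGFB2 (2.14 ± 0.111) and the potassium channel gene KCNC1 (2.11 ± 0.190).

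Of 42 estrogen-induced genes 31 were lower in starved medium and 2 higher (34 and 3 when adjusted over the list alone; camera adjusted p = 1.6e-25; adjusted p = 0.022 with an estimated correlation), with FHL2 at -1.69 ± 0.057. Estrogen-repressed genes were higher in 10 of 19 cases, including BCAS1 (1.72 ± 0.060) and LIPH (0.85 ± 0.076), and BCL6 was lower (-0.62 ± 0.059; 11 and 1 when adjusted over the list alone; camera adjusted p = 0.00020; adjusted p = 0.024 with an estimated correlation). Genes of DNA replication and division were lower. Of the G1/S list 24 of 29 genes fell, such as E2F7 (-0.78 ± 0.075) and RRM2 (-0.53 ± 0.059). CDK6 rose (1.08 ± 0.093; 24 and 1 when adjusted over the list alone; adjusted p = 0.0023 with an estimated correlation). Of the G2/M list 21 of 22 genes fell, such as TOP2A (-0.82 ± 0.079), TPX2 (-0.61 ± 0.058), NUSAP1 (-0.60 ± 0.062) and KIF11 (-0.48 ± 0.064; 22 when adjusted over the list alone; adjusted p = 0.040 with an estimated correlation). Ribosome biogenesis genes fell in 20 of 34 cases, including WDR74 (-0.68 ± 0.077), NOLC1 (-0.63 ± 0.094), NOP58 (-0.53 ± 0.075) and NPM1 (-0.46 ± 0.059; 23 when adjusted over the list alone; adjusted p = 0.016 with an estimated correlation).

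Cholesterol synthesis and uptake genes rose in 17 of 23 cases, including MSMO1 (1.15 ± 0.145), SC5D (1.04 ± 0.103) and the regulator gene SREBF2 (0.55 ± 0.063). A single gene fell (17 and 2 when adjusted over the list alone; camera adjusted p = 1.3e-06; adjusted p = 0.21 with an estimated correlation). Housekeeping genes, used as a reference group, fell in 8 of 17 cases and rose in 1 (8 and 1 when adjusted over the list alone; camera adjusted p = 0.032; adjusted p = 0.49 with an estimated correlation).

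With edgeR's quasi-likelihood test 2126 genes were higher and 2260 lower in starved medium, of which 367 and 279 changed at least 2-fold. The share of higher genes was 48.5%, and with library sizes not scaled by TMM it was 53.6%, 2357 higher and 2037 lower. Such scaled counts are relative, so a change shared by most genes would not be seen. With the library number as a block 2760 were higher and 2927 lower. DESeq2 called 1051 higher and 1250 lower. The total of 4386 became 2739 without starved vehicle library 3 and 2735 without starved vehicle library 4. It became 2555 without complete vehicle library 3 and 2875 without complete vehicle library 4. Of the 2260 genes lower in starved medium, 593 (26.2%) rose with estradiol and 43 fell. Of the 2126 higher, 492 fell with estradiol and 77 rose. Independent lists would share 113.8 and 79.5 genes in the opposite directions. Simulations with all 12 libraries redrawn and no gene changed shared 0.08 and 0.04 on average. These counts cannot show how many shared calls come from the shared vehicle libraries. The fold changes of both comparisons correlated across genes at r = -0.469, against -0.460 in the simulation. The covariance was -0.0868 against -0.0401, a difference of -0.0466. Part of the excess may come from the shared vehicle libraries. With 1 starved vehicle library given to each comparison, a split added after these values were seen, 357 and 347 genes in the 2 arrangements were lower in starved medium and raised by estradiol, against 45.1 and 40.3 for independent lists. In the other direction 241 and 253 were shared, against 25.3 and 25.5, and r was -0.2 in both arrangements. Levels after 1 h of estradiol were not tested against complete medium: GREB1 was at 1450 ± 55 and 1310 ± 62 CPM, and PDZK1 at 27.9 ± 0.41 and 77.1 ± 1.8 CPM.

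The drugs were compared with vehicle in complete medium, which asks what each ligand changes within 1 h where hormones are present. Fulvestrant lowered SPINK4 from 53.3 ± 4.4 to 13.6 ± 0.41 CPM, a log2 fold change of -1.96 ± 0.133. It lowered IGFBP4 from 135 ± 15 to 36.8 ± 1.4 CPM (-1.88 ± 0.099) and CXCL12 from 117 ± 2.4 to 32.2 ± 3.0 CPM (-1.86 ± 0.106). GREB1 changed by -1.15 ± 0.053 and MYC by -1.13 ± 0.098. ESR1 was lower by a small amount (-0.24 ± 0.040), and XBP1 did not pass (-0.34 ± 0.092, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.10). The few genes that rose did so by less, among them IL1R1 (0.57 ± 0.106), TCF7L1 (0.40 ± 0.069), the transporter gene ABCC5 (0.38 ± 0.051) and EPHA4 (0.37 ± 0.069).

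Of 42 estrogen-induced genes 26 fell with fulvestrant and 0 rose (31 when adjusted over the list alone), with a median of -0.67. This was the only one of the 20 lists called by camera or by fry's directional test (camera adjusted p = 7.3e-48, and adjusted p = 0.013 with an estimated correlation). Members included PDZK1 (-1.69 ± 0.122), RARA (-0.83 ± 0.063), NRIP1 (-0.78 ± 0.065), CA12 (-0.76 ± 0.052), PGR (-0.63 ± 0.058) and CCND1 (-0.59 ± 0.111). Outside that list PTGES (-1.65 ± 0.130), the galactosyltransferase gene B4GALT1 (-1.44 ± 0.071), the corticosteroid-binding globulin gene SERPINA6 (-1.37 ± 0.102) and GATA4 (-1.34 ± 0.134) fell. Smaller falls were seen for FKBP4 (-0.83 ± 0.072), IL6ST (-0.73 ± 0.068), FOSL2 (-0.68 ± 0.111) and IGF1R (-0.40 ± 0.044). BCL6 (-0.36 ± 0.059) and IGFBP5 (-0.41 ± 0.075), which stand in the estrogen-repressed list, fell too, and both had risen with estradiol. Of 23 cholesterol genes FDFT1 fell (-0.45 ± 0.088). Fry's mixed test also called the nuclear receptor, growth factor, heat shock, immediate-early and estrogen-repressed lists and the progestin, androgen and glucocorticoid targets (adjusted p from 5.7e-06 to 0.024).

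With edgeR's quasi-likelihood test fulvestrant lowered 245 genes and raised 25. With the library number as a block, a pairing that the labels do not state, 371 were lower and 127 higher. DESeq2 called 177 lower and 14 higher. Without complete vehicle library 3 the counts were 147 lower and 10 higher, without complete vehicle library 4 they were 160 and 7. Without fulvestrant library 3 they were 127 and 16, and without fulvestrant library 4 they were 182 and 15.

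Raloxifene lowered HEY2, a Notch-pathway repressor gene, from 17.7 ± 0.30 to 7.89 ± 1.7 CPM (-1.23 ± 0.194) and CLIC6, a chloride channel gene, from 33.7 ± 2.5 to 16.3 ± 1.4 CPM (-1.07 ± 0.132). CXCL12 (-0.95 ± 0.097), MYBL1 (-0.90 ± 0.100), KCTD6 (-0.87 ± 0.125), SERPINA6 (-0.86 ± 0.099) and IGFBP4 (-0.83 ± 0.090) fell as well. GREB1 changed by -0.47 ± 0.052, MYC by -0.68 ± 0.095, PDZK1 by -0.58 ± 0.109 and PGR by -0.29 ± 0.058. ESR1 (-0.12 ± 0.040), CCND1 (-0.34 ± 0.110) and XBP1 (-0.24 ± 0.092) did not pass. SF3B6 (0.52 ± 0.113), ABCC5 (0.40 ± 0.052), EPHA4 (0.38 ± 0.070), TCF7L1 (0.38 ± 0.070) and FNIP1 (0.36 ± 0.058) rose.

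Of 42 estrogen-induced genes 20 fell with raloxifene and 0 rose (30 when adjusted over the list alone), with a median of -0.39 (camera adjusted p = 3.7e-24; adjusted p = 0.076 with an estimated correlation). CA12 (-0.60 ± 0.052), RARA (-0.39 ± 0.063) and NRIP1 (-0.43 ± 0.064) were among them. Of 32 immediate-early genes MYC, KLF6 (-0.55 ± 0.108) and FOSL2 (-0.50 ± 0.110) fell (3 when adjusted over the list alone; camera adjusted p = 0.0028; adjusted p = 0.38 with an estimated correlation). In the growth factor list AREG (-0.64 ± 0.121), IL6ST (-0.61 ± 0.068), TGFA (-0.57 ± 0.110) and IGF1R (-0.19 ± 0.044) fell, of 21 tested (6 fell and 4 rose when adjusted over the list alone). The unfolded protein response (median 0.11) and the RNA polymerase III and snRNA genes (0.43) were called upward. The progestin, androgen and glucocorticoid targets and the p53 targets (-0.11 each) were called downward. These lists had 0 members past edgeR's quasi-likelihood test (camera adjusted p from 0.0028 to 0.047). When adjusted over the list alone, 2 p53 targets were lower. The estimated correlation among the RNA polymerase III and snRNA genes was 0.866, far above the preset 0.01. None of the 20 lists was called with an estimated correlation (adjusted p from 0.076 to 0.95). Fry called the estrogen-induced genes (adjusted p = 0.0026) and the progestin, androgen and glucocorticoid targets (adjusted p = 0.023) downward.

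Raloxifene library 4 stood apart from the others. Small nucleolar RNA genes held 0.113% of its counts (95% Wilson interval 0.110% to 0.116%), and at most 0.0430% (0.0412% to 0.0448%) of the counts of any other library. RMRP, a short RNA polymerase III gene, had a log2 fold change of 1.85 ± 0.702 with raloxifene that did not pass. By library totals without TMM, RMRP was at 32.6 CPM in raloxifene library 4 and 5.5 CPM in raloxifene library 3. RN7SK was at 28.0 and 9.3 CPM. Both genes stand in the RNA polymerase III and snRNA list, so its upward call may rest on raloxifene library 4. With edgeR's quasi-likelihood test raloxifene lowered 112 genes and raised 21. With the library number as a block 306 were lower and 184 higher. DESeq2 called 80 lower and 9 higher. Without raloxifene library 4 the counts were 140 lower and 62 higher, without raloxifene library 3 they were 56 and 148. Without complete vehicle library 3 they were 28 and 1, and without complete vehicle library 4 they were 53 and 3.

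Tamoxifen changed 12 genes by edgeR's quasi-likelihood test. With the library number as a block, a pairing that the labels do not state, 58 genes were higher and 114 lower. RUNX1, a transcription factor gene (ENSG00000159216, chromosome 21, 34787801 to 35049302), changed by -0.45 ± 0.050, MYBL1 by -0.67 ± 0.095, and PRAG1 by -0.51 ± 0.066. OLFM1 changed by -0.51 ± 0.090, B4GALT1 by -0.46 ± 0.066, PTP4A2 by -0.38 ± 0.065, IL6ST by -0.38 ± 0.066 and CA12 by -0.36 ± 0.050. Of the 12 genes, 3 further ones fell and ABCC5 alone rose (0.32 ± 0.051). GREB1 was 1100 ± 16 CPM with tamoxifen and 1310 ± 62 CPM with vehicle, a log2 fold change of -0.25 ± 0.052 that did not pass (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.098). IGFBP4 (-0.45 ± 0.084), PDZK1 (-0.28 ± 0.103), RARA (-0.32 ± 0.061), NRIP1 (-0.31 ± 0.062), MYC (-0.31 ± 0.090), XBP1 (-0.25 ± 0.091), PGR (-0.20 ± 0.058), CCND1 (-0.14 ± 0.106) and ESR1 (-0.08 ± 0.039) did not pass.

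Of 42 estrogen-induced genes 3 fell with tamoxifen (MYBL1, OLFM1 and CA12) and 0 rose. When adjusted over the list alone 24 fell, with a median of -0.25 (camera adjusted p = 2.3e-15; adjusted p = 0.20 with an estimated correlation). Immediate-early genes (median -0.19), progestin, androgen and glucocorticoid targets (-0.10), p53 targets (-0.10) and G2/M genes (-0.09) were called downward and ribosome biogenesis genes (0.07) upward. They had 0 members past edgeR's test, or 2 lower immediate-early genes when adjusted over the list alone (camera adjusted p from 1.0e-05 to 0.026). None of the 20 lists was called with an estimated correlation (adjusted p from 0.20 to 0.96). Fry called the estrogen-induced genes and the progestin, androgen and glucocorticoid targets downward (adjusted p = 0.034 each). The counts were 11 lower and 1 higher, with 1530 genes at an unadjusted p under 0.05. DESeq2 called 19 and 1. They became 0 and 0 without complete vehicle library 3, and 5 and 0 without complete vehicle library 4. They became 2 and 0 without tamoxifen library 3, 13 and 0 without tamoxifen library 4, and 28 and 1 in a fit without raloxifene library 4.

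**Figure D3:**
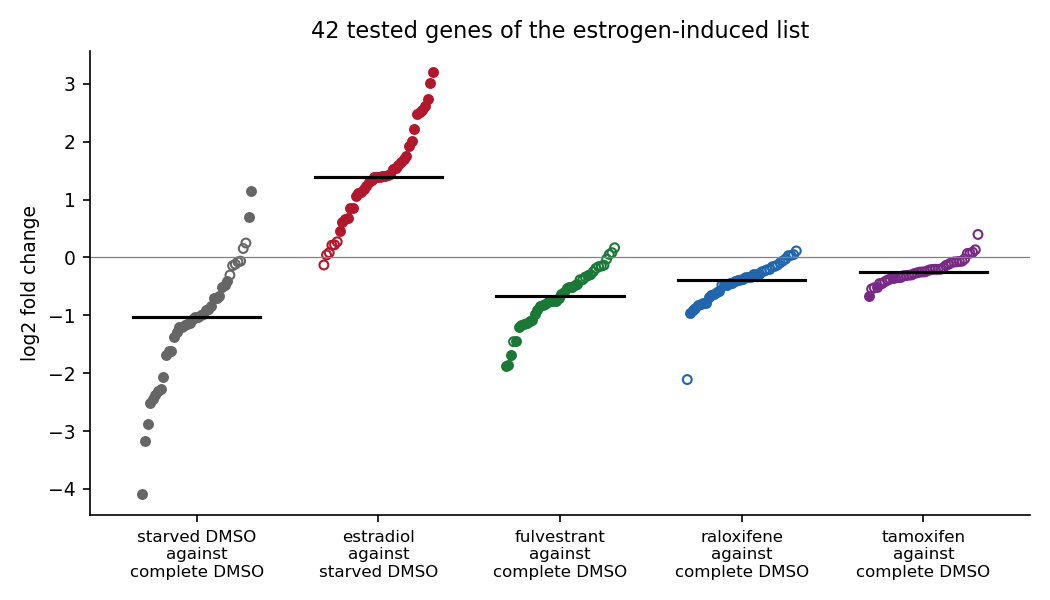
Log2 fold changes (vertical axis) of the 42 tested genes of the estrogen-induced list in 5 comparisons, sorted within each, with filled points past the threshold of an adjusted p under 0.05, open points not, and lines at the medians. The medians were -1.04 in starvation, 1.40 with estradiol, -0.67 with fulvestrant, -0.39 with raloxifene and -0.25 with tamoxifen.

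The drugs' calls were then set against those of estradiol, which share no libraries with them. Of the 245 genes lowered by fulvestrant, 235 (95.9%) were raised by estradiol, against 12.3 for independent lists. So were 104 of the 112 lowered by raloxifene (5.6 for independent lists) and 11 of the 11 lowered by tamoxifen (0.6). In the other direction, 24 of the 25 genes raised by fulvestrant and 13 of the 21 raised by raloxifene were lowered by estradiol. The genes raised by estradiol had a median log2 fold change of -0.16 with fulvestrant, -0.11 with raloxifene and -0.06 with tamoxifen, and those raised at least 2-fold had medians of -0.57, -0.34 and -0.20. This use of the estradiol calls was not among the tests fixed in advance. Camera with an estimated correlation gave p = 1e-04, p = 0.0011 and p = 0.015 for the 1177 raised genes, not adjusted over the 3 drugs.

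**Figure D4:**
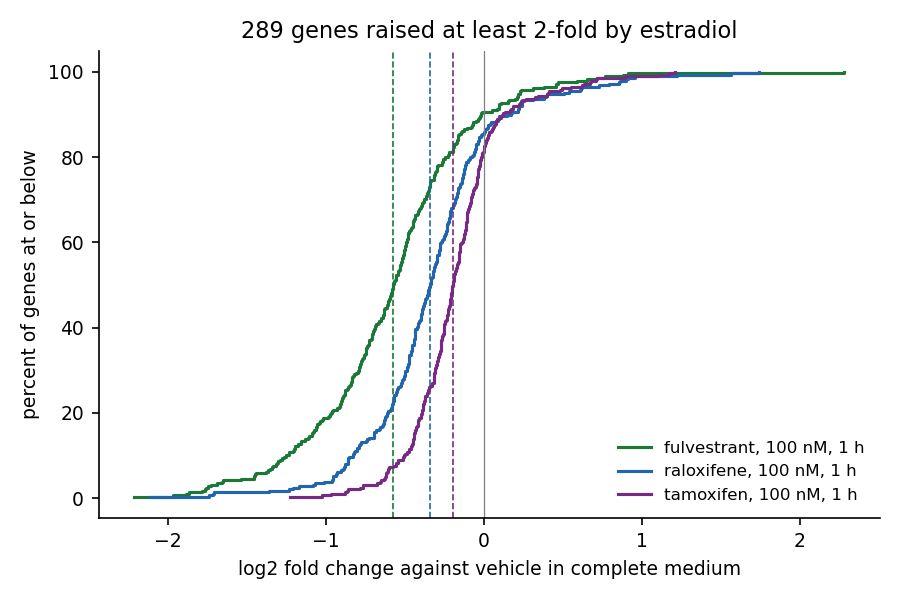
Percent (vertical axis) of the 289 genes raised at least 2-fold by estradiol whose log2 fold change against vehicle (horizontal axis) lies at or below each value, for the 3 drugs, with dashed lines at the medians. The medians were -0.57 for fulvestrant, -0.34 for raloxifene and -0.20 for tamoxifen.

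The drugs' calls also overlapped each other: 97 genes were lowered by both fulvestrant and raloxifene, 10 by both fulvestrant and tamoxifen, and 11 by both raloxifene and tamoxifen. Independent lists would share 1.2, 0.1 and 0.1 genes. Simulations with all 12 libraries redrawn and no gene changed shared 0.04, 0.04 and 0.08 on average, which cannot show how many shared calls come from the shared vehicle. Fold changes correlated across genes at 0.576, 0.580 and 0.608, against 0.506, 0.525 and 0.517 in the simulation. The covariances of 0.0641, 0.0544 and 0.0645 exceeded the simulated ones (0.0485, 0.0487 and 0.0485) by 0.0155, 0.0057 and 0.0160. Part of the excess may come from the shared vehicle libraries. With 1 vehicle library given to each drug, a split added after these values were seen, fulvestrant and raloxifene shared 27 and 41 lowered genes in the 2 arrangements, against 0.2 and 0.3 for independent lists, with r = 0.175 and 0.157. Both pairs with tamoxifen shared 0 and 5, where tamoxifen itself had 0 and 5 lowered genes by edgeR's quasi-likelihood test.

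The drugs were compared with each other at 100 nM and 1 h, which asks how far their effects differ at this dose and time. With a single dose and time, differences of ligand structure cannot be told apart from differences in receptor occupancy or speed of action. Fulvestrant is a steroid, an estradiol derivative with a long side chain, tamoxifen a triphenylethylene and raloxifene a benzothiophene. Against fulvestrant, tamoxifen left SPINK4 (1.52 ± 0.137), CXCL12 (1.51 ± 0.107), IGFBP4 (1.43 ± 0.101), PDZK1 (1.41 ± 0.123) and PTGES (1.35 ± 0.131) higher. The same held for GREB1 (0.90 ± 0.053), MYC (0.83 ± 0.099), RARA (0.51 ± 0.063), NRIP1 (0.46 ± 0.065) and PGR (0.42 ± 0.058). CCND1 (0.46, 95% interval 0.23 to 0.69), ESR1 (0.16, 0.08 to 0.24) and XBP1 (0.09, -0.10 to 0.28) did not pass. With edgeR's quasi-likelihood test 106 genes were higher with tamoxifen than with fulvestrant and 2 lower, one of them IFNGR1 (-0.71 ± 0.157). With the library number as a block 219 were higher and 23 lower. DESeq2 called 79 higher and 1 lower. The total of 108 became 48 without fulvestrant library 3 and 69 without tamoxifen library 4, and it was 66 when only these 2 groups were fitted.

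Raloxifene against fulvestrant gave 24 genes higher and 0 lower by edgeR's quasi-likelihood test, with 1146 genes at an unadjusted p under 0.05, where chance alone gives 1169. DESeq2 also called 24 and 0. With the library number as a block 75 were higher and 2 lower. SPINK4 (1.48 ± 0.141), PDZK1 (1.11 ± 0.129), IGFBP4 (1.06 ± 0.107), and PTGES (0.99 ± 0.14) were higher with raloxifene. So were CXCL12 (0.91 ± 0.116), B4GALT1 (0.82 ± 0.073), GATA4 (0.80 ± 0.143), GREB1 (0.68 ± 0.053), RARA (0.43 ± 0.065), NRIP1 (0.34 ± 0.066) and PGR (0.33 ± 0.058). MYC (0.45, 95% interval 0.23 to 0.67), CCND1 (0.25, 0.01 to 0.49), ESR1 (0.12, 0.04 to 0.20) and XBP1 (0.10, -0.09 to 0.30) did not pass. The total of 24 became 14 without either fulvestrant library and 168 without raloxifene library 3.

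Between tamoxifen and raloxifene a single gene passed, RUNX1, which was at 548 ± 0.47 CPM with tamoxifen and 430 ± 29 CPM with raloxifene, a log2 difference of 0.35 ± 0.051 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.024). GREB1 differed by 0.22 (95% interval 0.11 to 0.33), MYC by 0.37 (0.17 to 0.57), PDZK1 by 0.30 (0.07 to 0.53) and CCND1 by 0.21 (-0.02 to 0.43). NRIP1 differed by 0.12 (-0.01 to 0.26), PGR by 0.09 (-0.03 to 0.21), RARA by 0.08 (-0.05 to 0.21), ESR1 by 0.04 (-0.04 to 0.12) and XBP1 by -0.01 (-0.21 to 0.18). None of these 9 genes passed. A p that misses the threshold does not show that the drugs act alike. With the library number as a block, a pairing that the labels do not state, 26 genes were higher with tamoxifen and 9 lower. The intervals of GREB1, MYC and PDZK1 exclude 0, before any adjustment over genes. In the reported fit 1061 of all genes had an unadjusted p under 0.05, fewer than the 1169 that chance alone gives. Such a shortfall does not show that no gene differed. Raloxifene against fulvestrant fell short as well, at 1146, with 24 genes past the threshold. Between tamoxifen and raloxifene DESeq2 also called 1 gene. The count became 164 without raloxifene library 3, of which 162 were lower with tamoxifen, and 4 without raloxifene library 4. It became 0 without tamoxifen library 3, without tamoxifen library 4 or when only these 2 groups were fitted.

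The estrogen-induced list ranked the drugs in the same way. Its 42 genes had a median difference of 0.41 between tamoxifen and fulvestrant, with 18 genes higher (29 when adjusted over the list alone; adjusted p = 0.034 with an estimated correlation). The median was 0.21 between raloxifene and fulvestrant, with 9 higher (19 when adjusted over the list alone; adjusted p = 0.18 with an estimated correlation). Between tamoxifen and raloxifene the median was 0.14, with 0 genes past edgeR's quasi-likelihood test over all genes and 14 higher when adjusted over the list alone (adjusted p = 0.81 with an estimated correlation). Camera with the preset correlation gave adjusted p = 4.1e-33, 1.4e-16 and 5.9e-08 for the list in these comparisons, in this order. Fry gave adjusted p = 0.0015, 0.019 and 0.37. The genes raised by estradiol had median differences of 0.11, 0.06 and 0.07 in these comparisons, with p = 0.00028, p = 0.0072 and p = 0.0070 by camera with an estimated correlation, not adjusted over the comparisons. Of the 235 genes raised by estradiol and lowered by fulvestrant, 209 (88.9%) were lowest with fulvestrant and highest with tamoxifen among the 3 drugs, with medians of -0.59, -0.35 and -0.19. Because these genes were picked for their fall with fulvestrant, the position of fulvestrant in that order is partly set by the choice. Raloxifene lay below tamoxifen in 227 of them (96.6%). Among all 1177 genes raised by estradiol it lay below tamoxifen in 859 (73%), and among the 289 raised at least 2-fold in 228 (78.9%). Genes are not independent replicates, so these shares are not tests of the drugs.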

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

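The fit without raloxifene library 4 and the fit without short genes or genes lacking a length were chosen after the data had been seen. Of 1568 values of named genes under alternatives, 1403 kept direction and side of the threshold, 134 kept direction and lost the call, 27 kept direction and gained it, and 4 turned. Those 4 were not called: RN7SK with raloxifene (0.82) was 0.00 without raloxifene library 4 and 1.62 without raloxifene library 3. Between tamoxifen and raloxifene XBP1 was 0.15 without raloxifene library 4, 0.06 without tamoxifen library 3 and -0.21 without raloxifene library 3. Between raloxifene and fulvestrant it was -0.07 without raloxifene library 4 and 0.29 without raloxifene library 3. No gene called in both the reported fit and an alternative changed sign. The share of higher genes among those changed by estradiol went from 57.4% to 45.7% with library sizes only, and in starvation from 48.5% to 53.6%. The longest entry per symbol was not run, since the count table gives no lengths, and with a library left out the lone library of its group was assumed to vary like the other groups.

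Counts that moved by more than 1.5 times are given next, and the cause was not tested unless fewer libraries, other genes tested or a fold limit explain it by construction. DESeq2 called 702 genes higher and 376 lower with estradiol, 14 higher with fulvestrant, 9 higher with raloxifene, 19 lower with tamoxifen and 2301 in starvation. The robust fit gave 38 higher with fulvestrant, 19 lower with tamoxifen and 4 between tamoxifen and raloxifene. Library sizes only gave 42 higher with fulvestrant and 32 with raloxifene, and a mean of at least 50 counts gave 37 higher with raloxifene. Without the filter there were 59 higher with fulvestrant, 132 higher and 222 lower with raloxifene, 24 and 69 with tamoxifen, and 65, 170 and 90 for tamoxifen against raloxifene, tamoxifen against fulvestrant and raloxifene against fulvestrant. Fits of only the groups compared gave 39 higher with fulvestrant, 20 lower with tamoxifen, 0 between tamoxifen and raloxifene and 66 between tamoxifen and fulvestrant. Without genes under 1000 bases or lacking a length, 17 were lower with tamoxifen and 2 differed between tamoxifen and raloxifene, and the fit without raloxifene library 4 gave 39 higher with fulvestrant and 28 lower with tamoxifen. With an estimated correlation 3 of the 8 lists called for estradiol were called, and 5 to 7 with a library left out.

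A test against a 1.5-fold change called 249 genes higher and 17 lower with estradiol, 26 lower and 0 higher with fulvestrant, 0 and 0 with raloxifene and with tamoxifen, 0 between tamoxifen and raloxifene, 8 between tamoxifen and fulvestrant, 1 between raloxifene and fulvestrant, and 470 in starvation. Leaving out each library in turn gave 701 to 822 higher and 443 to 504 lower with estradiol, 7 to 16 and 127 to 182 with fulvestrant, 1 to 148 and 28 to 140 with raloxifene, and 0 and 0 to 13 with tamoxifen. It gave 0 to 164 between tamoxifen and raloxifene, 48 to 86 between tamoxifen and fulvestrant, 14 to 168 between raloxifene and fulvestrant, and 2555 to 2875 in starvation.

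The labels do not say that libraries of the same number were made together, so they were not treated as pairs. Their within-group differences correlated between groups with r from 0.047 to 0.362, over 0.1 in 10 of 15 pairs of groups, where all 15 were required. At genes with a mean of at least 200 counts r ran from 0.168 to 0.508, over 0.1 in 15 of 15, so a shared preparation stays possible. A replicate block on the library number gave 1407 genes lower with estradiol, 127 higher and 371 lower with fulvestrant, 184 and 306 with raloxifene, 58 and 114 with tamoxifen, 35 between tamoxifen and raloxifene, 242 between tamoxifen and fulvestrant, and 77 between raloxifene and fulvestrant. Depth limits the low genes: TFF1 had 56 counts in all and was not tested.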

Other observations

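The explanations of the length, neighbour and library-number patterns below, with their predictions, were written before their results were seen. The length trend of genes that starvation raised and estradiol lowered was chosen after its result was seen. No prediction was written for pairs of lowered genes, the further gaps, genes with a mean of at least 200 counts or the principal components. The rules that judged the length explanations were corrected to follow the written predictions after the values had been seen. In starved cells single members of lists not described above changed, and camera called none of these lists (adjusted p from 0.15 to 0.91), while fry called 6 of them: the nuclear receptor, p53, luminal, basal and mesenchymal, growth factor and interferon lists (adjusted p from 0.0010 to 0.041). The receptor gene EGFR (1.03 ± 0.080, log2 fold change with the standard error of the fit, n = 2) and the matrix gene FN1 (0.96 ± 0.138) were higher than in complete medium. CD44 was lower (-0.45 ± 0.138), of 13 basal and mesenchymal markers (2 rose, 1 fell, the same when adjusted over the list alone). Of 21 growth factor genes 5 rose and 6 fell, the same when adjusted over the list alone, with AREG at -1.61 ± 0.129 and the receptor gene ERBB4 at -0.84 ± 0.060. Immediate-early genes went both ways, with 9 of 32 higher, including JUN (1.02 ± 0.097) and CCN1 (0.84 ± 0.095), and 5 lower, including IER5 (-0.67 ± 0.100). Of 17 progestin, androgen and glucocorticoid targets 4 rose, and 2, ZBTB16 (-1.97 ± 0.192) and FKBP5 (-0.75 ± 0.059), fell (4 and 2 when adjusted over the list alone; camera adjusted p = 0.70). Of 16 heat shock genes 4 rose, including HSPB1 (1.04 ± 0.116), and FKBP4 fell (-0.93 ± 0.071; 4 and 2 when adjusted over the list alone). Interferon-stimulated genes rose in 5 of 22 cases and none fell, with a median of 0.23 (camera adjusted p = 0.15).

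Estradiol moved few members of the remaining lists, none of which camera or fry's directional test called. Fry's mixed test called the cholesterol genes (adjusted p = 5.8e-05), the p53 targets and the housekeeping genes (adjusted p = 4.6e-05 each). It did not call the BCL2 family (adjusted p = 0.13) or the RNA polymerase III and snRNA genes (adjusted p = 0.8). Of 23 cholesterol genes FDFT1 (0.63 ± 0.082) and CYP51A1 (0.41 ± 0.108) rose. Of 18 p53 targets AEN rose (0.77 ± 0.146) and DDB2 (-0.36 ± 0.080) and TP53INP1 (-0.35 ± 0.094) fell. Among 17 housekeeping genes 4 rose, such as EEF1A1 (0.23 ± 0.056), and ENO1 fell (-0.33 ± 0.081; 6 and 2 when adjusted over the list alone). None of 14 BCL2 family genes and none of 14 RNA polymerase III and snRNA genes passed edgeR's quasi-likelihood test, which over all genes had 4460 with an unadjusted p under 0.05. The immediate-early gene KLF6 fell with fulvestrant (-0.45 ± 0.106) and raloxifene (-0.55 ± 0.108) and did not pass with estradiol (0.22, a value chosen after it was seen). It is one of 10 genes lowered by fulvestrant and 8 lowered by raloxifene that were not called for estradiol.

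Transcription takes time to travel along a gene, so genes that starvation lowered and estradiol raised might have fallen short of their complete-medium level more when long. Among 535 of the 593 such genes with a known length, the Spearman correlation of length with the log2 ratio of estradiol to complete medium, adjusted for expression, was 0.036, so no shortfall growing with length was seen among these genes, which were picked for having risen. A shortfall limited to the longest is not excluded: the median log2 ratio was 0.07 for 77 genes of 100 to 200 kb and -0.05 for 49 genes over 200 kb, a difference that was not tested. A length trend at all genes stays open, since genes called in neither comparison gave -0.082 and 77.2% of them had a length, and so does an effect of higher counts in long genes, since the unadjusted correlation of 0.04 left no trend to remove. The opposite set, raised by starvation and lowered by estradiol, gave 0.179 over 439 genes (permutation p = 2e-04), seen after the tests were chosen.

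Genes raised by estradiol lay near each other more often than genes of like expression with shuffled calls. Pairs 10 to 250 kb apart were 2.05 times as frequent and pairs 50 to 250 kb apart 1.78 times (permutation p = 0.001 each, the smallest that 1000 shuffles can give), which argues against shared annotation and read-through as the whole cause. Regulation shared over a chromosomal domain is a candidate explanation, since the ratio was lower, 1.27, at 1 to 2 Mb, with 1043 of the 1177 genes placed. The decline was not steady: the ratios were 3.92 for overlapping genes, 3.94 up to 10 kb, 2.98 at 10 to 50 kb, 1.78, then 1.00 at 250 kb to 1 Mb and 1.27, and shuffles of single genes understate the spread at long range. Genes lowered by estradiol gave smaller ratios: 2.47, 2.00 and 1.48 up to 50 kb, 123 pairs against 98.8 with shuffled calls at 50 to 250 kb (permutation p = 0.017), and 0.79 and 0.91 beyond 250 kb.

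Libraries numbered 3 and libraries numbered 4 deviated together: the differences within groups correlated on average with r = 0.148 over 15 pairs of groups, and with r = 0.297 at genes with a mean of at least 200 counts. Each of the first 3 principal components (28.9%, 15.1% and 11.9% of the variance) ordered the libraries numbered 3 and 4 the same way in 6 of 6 groups. The mean correlation was 0.106 after every library was thinned to the lowest total and 0.143 without small RNA genes and genes under 1000 bases. Neither depth nor these genes alone therefore account for all of it. Thinning left 6 of 15 pairs over 0.1, against 10 before, so a part due to depth is not excluded. Both changes together were not tried. The labels name no batch, and no biological explanation was tested.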
